A study of Schmidtea mediterranea with 15 samples.

How the data were processed

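The samples were 15 poly(A)-selected RNA libraries of the planarian flatworm Schmidtea mediterranea, from animals that the labels name as the sexual S2F2 biotype. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a TruSeq RNA kit, whose protocol does not record the strand of the RNA. The libraries fall into 5 groups of 3, taken from the sample titles: trunk fragments at day 0, regenerating fragments at days 3, 5 and 7, and whole intact juvenile animals. The labels do not say whether replicates came from separate animals or pools, so p-values measure the spread between these samples, which may be technical in part. Juveniles differed from day 0 fragments in body part (whole animal against trunk) and in stage together, and these cannot be separated with these libraries.

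The deposited values are raw read counts, 1 row per sequence record and 1 column per library, with no normalization applied, as judged from the values (whole numbers with differing column totals). Per the submitters' processing notes the authors used Bowtie2; its version and settings, the counting tool, the sequence set that the reads were aligned to and any filter are not given in the sources used here. The table had 92053 records, of which 91522 carried identifiers in the format of 1 transcriptome assembly project and 531 carried other identifiers; 280 had no count in any library. The files do not pair the identifiers with gene names, and no genome or annotation was used here. For that reason the 20 gene lists fixed in advance (stem cells, wound response, organ and germ cell markers and others) could not be matched and no list was tested. Records are called transcripts here, but several can represent 1 gene: 1298 rows were identical to an earlier row, and 188 of the 276 records with other identifiers above a mean CPM (counts scaled to library size) of 10 had an assembly-project record within 10% of their count in every library. Counts of transcripts are therefore not counts of genes, and how reads shared between near-identical records were assigned is not given in the sources used here. Overlapping transcripts of opposite strand cannot be told apart with this kit.

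Total counts ranged from 20338464 (day 0 replicate 1) to 59034917 (day 5 replicate 1). Low-count records were removed with filterByExpr (minimum count 10, minimum total count 15, on the 5 groups), which left 46736 records holding at least 99.6% of the counts of each library. The most abundant record took between 6.96% and 9.29% of a library. Counts were scaled by the trimmed mean of M-values (TMM), with factors from 0.893 to 1.12, and tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1): 1 robust quasi-likelihood fit of all 15 libraries with group as the only term and 10 residual degrees of freedom, and Benjamini-Hochberg adjustment over all records tested. A transcript was called at an adjusted p under 0.05. The median log2 fold change over all records was at most 0.0633 in size in each comparison. An F test with 3 degrees of freedom asked for any difference among the 4 trunk groups. CPM values use the TMM-scaled library sizes, and shares are percentages of a library's total count.

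The design implied 7 pairwise comparisons and the F test, and these, their tests, the alternatives and the rule for named transcripts were fixed before the data were examined. The rule, for identifiers without names, took the 2 rising and the 2 falling transcripts with the smallest adjusted p in the tests of days 3, 5 and 7 against day 0. Added after the data were seen were the comparisons of day 7 with day 3, and of days 3 and 5 with juveniles, the counts of transcripts above or below both day 0 and juveniles, and sets of transcripts defined by the juvenile comparison. Juvenile-low transcripts were called lower in juveniles than at day 0 by at least 4-fold, and juvenile-high transcripts higher by at least 4-fold. Juvenile-low transcripts that were called higher at day 7 than at day 0 are termed rising. The others were split by their correlation with the first principal component of the deviations of log2 CPM (prior count 2) from group means over the 12 trunk libraries: at 0.8 or above they are termed co-varying, under 0.5 steady, and between these intermediate. A low spread of the steady set between replicates is partly a product of that rule. The libraries of days 3, 5 and 7 entered the filter and the spread of the fit that chose these sets. For a test of their shares over those days, juvenile-low and juvenile-high transcripts were therefore chosen again in a fit of day 0 and juveniles alone, and the shares were compared by a two-sided exact permutation test over 1680 arrangements of the 9 libraries, adjusted over 2 sets. This choice was made after the data were seen. The same test on the 6 sets of the fit of all libraries is not given, since these libraries helped to choose them. A test of 3 libraries against 3 cannot give a p below 0.1.

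Comparisons that use the same day 0 libraries share their chance values. The simulations of day 7 beside juveniles were added after the data were seen. Overlaps of calls are given beside 10 simulations of unchanged groups sharing those libraries and beside the overlap of independent lists; correlations and covariances of log2 fold changes are given beside 100 random regroupings of the libraries after each group's mean was removed. With 3 day 0 libraries, the control could not be divided into parts of at least 2. In the check of replicate numbers, deviations of same-numbered libraries from their group means correlated at 0.24, 0.174 and 0.515 for day 3 and day 0. Each value was above 0.1, and each of the 3 correlated best with its own number. This comes from the data, since the labels do not say what a number stands for. Deviations within a group sum to 0, so the 3 values are not independent. Replicate 3 lay apart in both groups, which by itself raises the values of numbers 1 and 2. They therefore do not establish that the numbers pair the libraries. In the other 9 comparisons at least 1 number fell to 0.1 or below.

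Counts were simulated for day 3 against day 0, with 45166 records tested and 200 changed. The test recovered 6% of records changed 1.5-fold, 52% at 2-fold, 74% at 4-fold and 82% at 8-fold, with 4 false calls. These counts were drawn independently for each record. The 4 therefore do not measure false calls from differences that many records share between libraries. Alternatives were DESeq2 size factors (RLE) in place of TMM, no low-count filter, DESeq2 1.42.0, a fit of only the groups compared (where a record that a fit did not test counts as not called in it), the replicate number as a block, a 2-fold threshold, and leaving out each library in turn. Chosen after the data were seen were leaving out 3 libraries together and 2 other folds for the juvenile-low set. The 3 were day 0 replicate 3, day 3 replicate 3 and day 7 replicate 2. They were picked by their positions and not by a fixed rule of distance. Day 7 replicate 3 lay about as far from its group and was kept.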

Results

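RNA abundance was measured by poly(A) RNA sequencing in trunk fragments of sexual Schmidtea mediterranea, a planarian that rebuilds missing body parts after amputation, and in whole juvenile animals. Fragments were sampled at day 0 and after 3, 5 and 7 days of regeneration, with 3 libraries per group. Total counts were 20338464 to 34569921 per library at day 0, 36859187 to 52422628 at day 3, 36927291 to 59034917 at day 5, 45862344 to 50684775 at day 7 and 25735815 to 37791352 in juveniles. Of 92053 sequence records, 46736 had enough counts to be tested. The first principal component of log2 CPM (read counts scaled to library size) carried 66.6% of the variance. Day 0 libraries lay at scores of -178 to -105 on it and juveniles at 156 to 174, with the regenerating libraries between. Libraries of 1 trunk group differed widely on this component: day 0 replicate 3 lay at -178 against -105 and -106, day 3 replicate 3 at -95.3 against -11.4 and -16.1, and day 7 replicates at 51.5, 123 and 1.34.

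**Figure D1:**
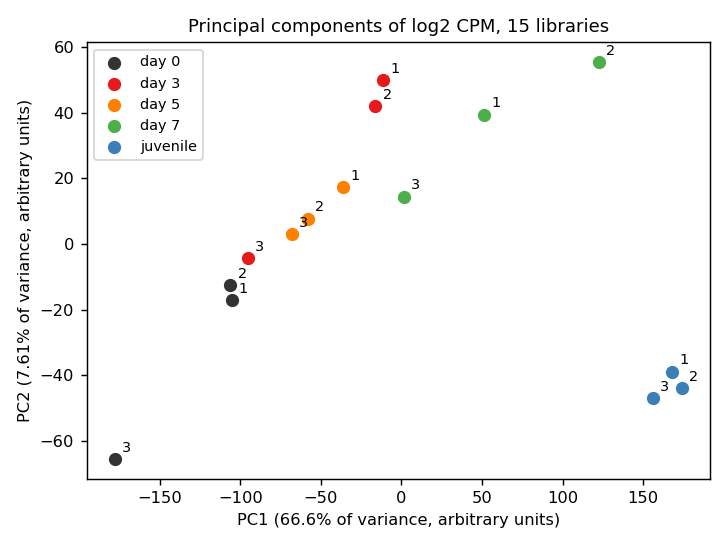
Principal components of log2 CPM over the 15 libraries, with the first component (66.6% of variance) on the horizontal and the second (7.61%) on the vertical axis, both in arbitrary units. Points are libraries, coloured by group and numbered by replicate; juveniles lie together at the right, and the trunk libraries spread between -178 and 123.

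Day 3 fragments were compared with day 0 fragments to find transcripts that change early in regeneration. At day 3, 1410 transcripts were higher and 2563 lower, of which 329 and 557 changed at least 2-fold. The most significant fall was that of GDAG01033469.1, which went from 35.2 ± 5.45 CPM at day 0 to 1.24 ± 0.256 CPM at day 3 (SD, n = 3 each), a log2 fold change of -4.82 (SE 0.19, edgeR adjusted p = 5e-09). GDAG01017044.1 rose from 4.21 ± 0.61 to 21.3 ± 3.47 CPM, a log2 fold change of 2.34 (SE 0.14, edgeR adjusted p = 1.7e-07). GDAG01071011.1 rose from 14.9 ± 1.36 to 33.5 ± 0.468 CPM, or 2.26-fold (SE 0.1 on the log2 scale, edgeR adjusted p = 1e-05). GDAG01016573.1 fell by 0.58 on the log2 scale (SE 0.12, edgeR adjusted p = 0.0069). These 4 were taken by the rule for named transcripts, and the files do not pair them with gene names. With the replicate number as a block, 7238 transcripts were called, 75.1% of them lower, against 3973 and 64.5% without it. The count was 2241 without day 3 replicate 1, 1795 without day 3 replicate 2, and 664 when day 0 and day 3 were fitted alone.

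At day 5, 1510 transcripts were higher and 2638 lower than at day 0, of which 260 and 650 changed at least 2-fold. GDAG01017044.1 was at 17.8 ± 2.2 CPM, 4.23-fold over day 0 (edgeR adjusted p = 9.4e-07), and GDAG01071011.1 at 29.3 ± 2.48 CPM, 1.97-fold over day 0 (edgeR adjusted p = 2.6e-05). GDAG01033469.1 was still 5.89-fold lower than at day 0, and GDAG01016573.1 was 2.15-fold lower (edgeR adjusted p = 2.5e-06 and 4.1e-05). The count of 4148 transcripts was 2331 without day 5 replicate 2, 2538 without day 5 replicate 3, and 2103 when day 0 and day 5 were fitted alone.

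The step from day 3 to day 5 changed few transcripts at this depth and spread. Only 9 of 46736 passed the edgeR test, 8 higher and 1 lower at day 5, while 3034 had an unadjusted p under 0.05 and DESeq2 called 71, 36 higher and 35 lower. The split by direction rested on few calls: without day 3 replicate 2 it was 3 higher and 5 lower. Of the 8 that rose, 7 belonged to the 100 transcripts that were at least 4-fold higher in juveniles than at day 0. The other was GDAG01033469.1, which climbed from 1.24 ± 0.256 to 5.98 ± 1.11 CPM, a log2 fold change of 2.26 (SE 0.18, edgeR adjusted p = 9e-05), after its fall at day 3. The count was 3 without day 3 replicate 3 or without day 5 replicate 1, 22 without day 0 replicate 3, 4 when the 2 groups were fitted alone and 21 without the low-count filter. Leaving out day 0 replicate 3, day 3 replicate 3 and day 7 replicate 2 together, chosen after their positions had been seen, gave 539.

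Day 7 fragments differed from day 0 in more transcripts than the earlier days did: 3676 were higher and 7487 lower, of which 718 and 4161 changed at least 2-fold. GDAG01016573.1 had fallen from 24.8 ± 3.14 to 4.68 ± 0.744 CPM, a log2 fold change of -2.41 (SE 0.13, edgeR adjusted p = 3.3e-08). GDAG01017044.1 was at 18.9 ± 1.82 CPM, 4.5-fold over day 0, with a log2 fold change of 2.17 (SE 0.14, edgeR adjusted p = 9.3e-08). GDAG01071011.1 was at 36.8 ± 5.16 CPM, with a log2 fold change of 1.31 (SE 0.1, edgeR adjusted p = 5.5e-07), and GDAG01033469.1 at 6.74 ± 1.07 CPM, 5.22-fold below day 0. The count of 11163 transcripts was 7031 without day 0 replicate 3, 6510 without day 7 replicate 1, and 5162 when day 0 and day 7 were fitted alone.

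**Figure D2:**
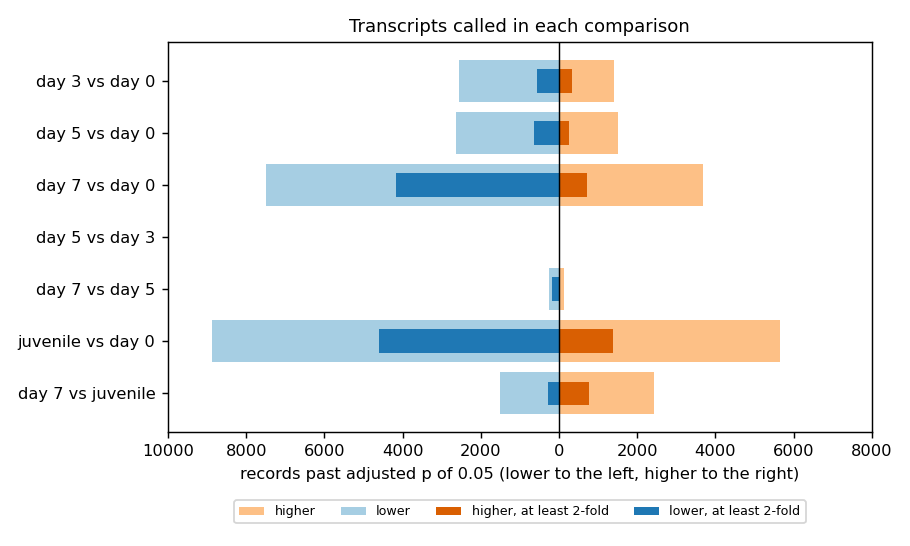
Numbers of transcripts past an adjusted p of 0.05 (edgeR quasi-likelihood test) in each of the 7 comparisons, with those lower in the first-named group drawn to the left and those higher to the right; the narrow dark bars count those that also changed at least 2-fold. Calls against day 0 were similar in number at days 3 and 5 (3973 and 4148), higher at day 7 (11163), and highest for juveniles (14530); day 5 against day 3 has 9.

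From day 5 to day 7, 131 transcripts rose and 243 fell, and 166 of those that fell did so by at least 2-fold. Of these 243, 161 were steady juvenile-low transcripts, the set defined under the juvenile comparison. The choice of that set used the day 5 and day 7 libraries and favours a small spread, so this count is not independent of it. GDAG01016573.1 fell by 1.3 on the log2 scale in this step (SE 0.12, edgeR adjusted p = 0.00011), while GDAG01017044.1 and GDAG01071011.1 did not pass the test (adjusted p = 0.8 and 0.17). Leaving out day 5 replicate 1, 2 or 3 gave 199, 174 and 197 calls in place of 374, leaving out day 7 replicate 1, 2 or 3 gave 232, 196 and 239, and leaving out day 0 replicate 3 gave 613. A fit of these 2 groups alone called 914, DESeq2 called 1235, and the fit without the 3 libraries left out together called 1578.

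Over the 4 trunk groups together, the F test called 6687 of 46736 transcripts (14.3%). Sorted by their calls against day 0, 692 transcripts were higher and 1617 lower at all 3 later days. A further 2074 were called higher and 4696 lower at day 7 alone, 244 higher and 193 lower at day 3 alone, and 260 higher and 254 lower at day 5 alone; these classes count calls and do not test one day against another. No transcript was called in opposite directions at 2 days: the edgeR tests found 0 higher at day 3 and lower at day 7, and 0 the other way. The lists of day 3 and day 7 shared 1105 transcripts higher and 2197 lower, against 110.9 and 410.6 for independent lists and a mean of 0.1 in simulations of unchanged groups with the same day 0 libraries, a value that leaves out all effects and is near 0 because such groups give few calls. Part of the excess may come from the shared day 0 libraries, which could not be divided. The F test called 4440 transcripts without day 7 replicate 1 and 4426 without day 7 replicate 2. The 2309 transcripts called alike at all 3 days were 1281 without day 3 replicate 2, 500 when groups were fitted in pairs and 402 at a 2-fold threshold. With the replicate block they were 3719. Same-numbered libraries correlated above 0.1 for all 3 numbers only between day 3 and day 0.

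Intact juveniles were compared with day 0 fragments, a difference of body part and stage together. In juveniles 5661 transcripts were higher and 8869 lower, of which 1384 and 4599 changed at least 2-fold. A set of 3490 transcripts was at least 4-fold lower in juveniles and is called juvenile-low. It took 12.1% ± 1.56 of the counts at day 0 and 0.329% ± 0.0601 in juveniles (SD, n = 3). The 100 transcripts at least 4-fold higher, called juvenile-high, were scarce in both groups, with 0.00269% ± 0.000465 of the counts at day 0 and 0.040% ± 0.00627 in juveniles. GDAG01016573.1 was among the juvenile-low transcripts, with 24.8 ± 3.14 CPM at day 0 and 0.0414 ± 0.0206 CPM in juveniles, where it had 4 counts over the 3 libraries. GDAG01033469.1 was 15.7-fold lower in juveniles (2.24 ± 0.0924 CPM, edgeR adjusted p = 9.7e-10). GDAG01017044.1 fell by 0.48 on the log2 scale (SE 0.14, edgeR adjusted p = 0.014), and GDAG01071011.1 did not pass the test (14.9 ± 1.36 against 14.0 ± 1.38 CPM, adjusted p = 0.59). The most abundant juvenile-low transcript alone took 1.96% ± 0.463 of the counts at day 0 and 0.00318% ± 0.000971 in juveniles. The juvenile-high set had 198, 278 and 260 transcripts without day 0 replicate 1, 2 or 3, 156 without day 3 replicate 2, 159 without day 5 replicate 2, and 316 without the low-count filter; when day 0 and juveniles were fitted alone the sets were 61 juvenile-high and 3037 juvenile-low transcripts.

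Of the 3490 juvenile-low transcripts, 3315 (95%) were called lower at day 7 than at day 0. This majority was lost when 1 of 2 libraries was left out: 1504 of 3155 (47.7%) without day 0 replicate 3 and 1535 of 3678 (41.7%) without day 7 replicate 1. In fits of only the groups compared it was 804 of 3037 (26.5%). The set was chosen as high in the same day 0 libraries. In 10 simulations with juveniles as observed and day 7 unchanged from day 0, edgeR called 0 of a mean of 3394.2 juvenile-low transcripts lower. These simulations drew transcripts independently and took the observed day 0 means as true levels. Their 0 therefore does not measure what the choice of the set, or differences that many transcripts share between libraries, adds to the 3315. The share of counts taken by the whole set went from 12.1% ± 1.56 at day 0 through 7.71% ± 1.1 at day 3 and 7.18% ± 0.354 at day 5 to 5.68% ± 1.43 at day 7. For the 3037 juvenile-low transcripts of the fit of day 0 and juveniles alone, the shares of 7.68% ± 1.09, 7.15% ± 0.355 and 5.66% ± 1.43 at days 3, 5 and 7 did not pass an exact permutation test (p = 0.0964, adjusted p = 0.0964). Either sum joins members that rose with members that fell. Without the 32 rising transcripts described next, the set of 3490 took 5.17% ± 1.38 at day 3, 4.07% ± 0.482 at day 5 and 1.64% ± 0.743 at day 7, where the highest library (2.29%) lay below the lowest of days 3 and 5 (3.9% and 3.67%); the rising transcripts were chosen with day 7, so no test of these shares is given. A steady part of 615 transcripts, which did not follow the main difference between replicates, took 7.33% ± 1.38, 3.64% ± 0.593, 2.41% ± 0.449 and 1.2% ± 0.644 of the counts at days 0, 3, 5 and 7, and 0.0624% ± 0.0069 in juveniles. Its 10 most abundant transcripts held 72% of its counts at day 0 and 66.8% at day 7, so these shares describe mostly those. Among day 7 libraries its highest share was 2.76 times the lowest. The split into steady and co-varying parts used the libraries of days 3, 5 and 7 and favours a small spread in the steady part, so its p-values over these days are not given and its counts of calls are not independent of the choice. Steady transcripts called lower than at day 0 numbered 228, 414 and 562 at days 3, 5 and 7, and 242 were lower at day 7 than at day 3. A co-varying part of 2530 transcripts took 3.71% ± 2.45, 1.48% ± 1.21, 1.60% ± 0.492 and 0.424% ± 0.357 of the counts at days 0, 3, 5 and 7, and 0.148% ± 0.0184 in juveniles. Its spread within a group was large, with a highest share 6.93 times the lowest among day 7 libraries. Of the co-varying transcripts 2473 were called lower at day 7 than at day 0. Without day 0 replicate 3 and without day 7 replicate 1 this count was 766 and 769. The 228 steady transcripts lower at day 3 became 123 without day 3 replicate 2. The 242 became 109 without the 3 libraries left out together. In fits of only the groups compared, where 2328 juvenile-low transcripts were co-varying and 521 steady, 290 of the co-varying ones were lower at day 7 than at day 0, and those of steady transcripts lower at day 3 than at day 0 and lower at day 7 than at day 3 were 126 and 155.

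A rising part of 32 juvenile-low transcripts went the other way. It took 1.02% ± 0.0654 of the counts at day 0, 2.54% ± 0.34 at day 3, 3.11% ± 0.309 at day 5 and 4.04% ± 0.718 at day 7, against 0.11% ± 0.0361 in juveniles (SD, n = 3). All 32 were higher at day 7 than at day 0 by definition, and 18 were already higher at day 3 and 18 at day 5. Between the later days themselves edgeR called 0 of the 32: from day 3 to day 5, where 0 had an unadjusted p under 0.05 and DESeq2 called 0, from day 5 to day 7, where 9 had one, all higher, and DESeq2 called 1 higher, and from day 3 to day 7, where 19 had one, all higher, and DESeq2 called 10 higher. The set was chosen with day 7, so no test of its share over these days is given. The 10 most abundant of the 32 held 94.6% of the set's counts at day 7. In each of the 3 day 7 libraries this part held more counts than all other juvenile-low transcripts together. At a 2-fold bound for the juvenile-low set 54 transcripts were rising, and at 8-fold 19.

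Of the 100 juvenile-high transcripts, 13 were called higher than at day 0 at day 3, with 1 called lower, 35 were higher at day 5 and 55 at day 7. Their share of counts went from 0.00269% ± 0.000465 at day 0 to 0.00549% ± 0.000765 at day 3, 0.0201% ± 0.00266 at day 5 and 0.040% ± 0.00103 at day 7, beside 0.040% ± 0.00627 in juveniles. The set was chosen as low in the same day 0 libraries, which favours calls above day 0. Among the 43146 tested transcripts outside the juvenile-low and juvenile-high sets, 3.19%, 3.37% and 8.32% were called higher at days 3, 5 and 7. The day 3, 5 and 7 libraries also entered the fit that chose this set. For the 61 juvenile-high transcripts of the fit of day 0 and juveniles alone, the summed share was 0.00474% ± 0.000723, 0.0193% ± 0.00269 and 0.0394% ± 0.000993 at days 3, 5 and 7, and it differed among these days (exact permutation p = 0.00357, adjusted p = 0.00714). At day 7, 38 were still called lower than in juveniles and 2 higher. The 10 most abundant held 92.5% of the set's counts at day 7, and the median transcript of the set stayed lower, at 0.28 ± 0.00992 CPM against 0.54 ± 0.0227 CPM in juveniles. The 55 became 83, 119 and 91 without day 0 replicate 1, 2 or 3, where the set was larger, 99 without the low-count filter and 29 when only the groups compared were fitted.

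**Figure D3:**
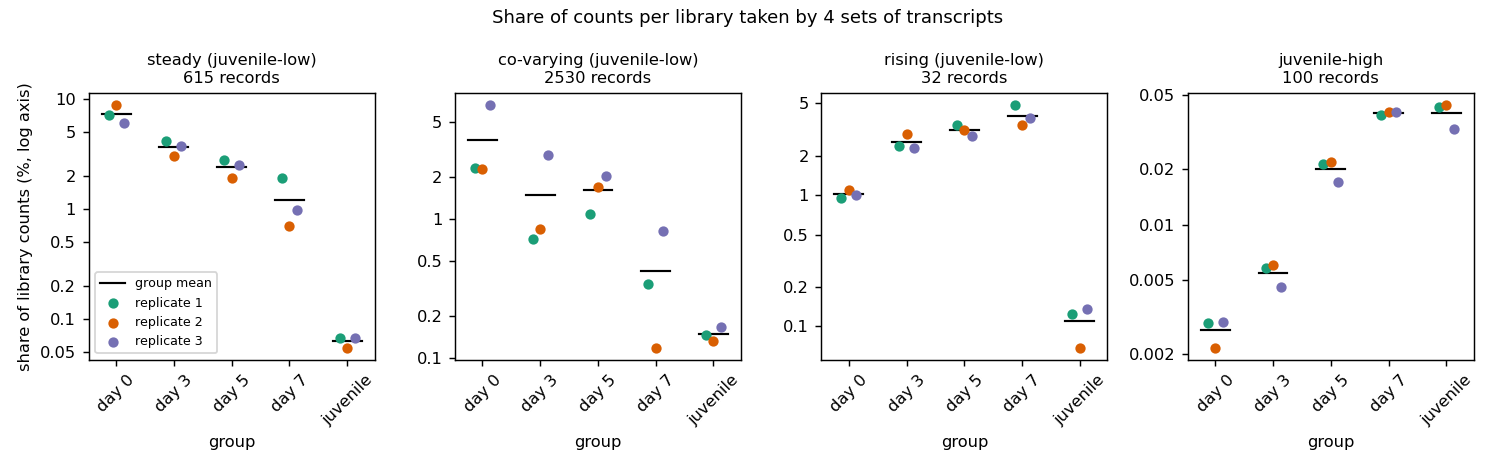
Share of each library's counts (percent, log axis) taken by the steady, co-varying and rising juvenile-low transcripts and by the juvenile-high transcripts, by group on the horizontal axis. Points are libraries coloured by replicate number and bars are means of 3; steady transcripts lie at 7.33% at day 0 and 1.2% at day 7, rising transcripts climb from 1.02% to 4.04%, and juvenile-high transcripts go from 0.00269% to 0.040%.

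Day 7 fragments were compared with juveniles to find what separated the regenerates from intact small animals. At day 7, 2433 transcripts were higher and 1500 lower than in juveniles, of which 776 and 274 differed at least 2-fold. Among the 2433 were 472 juvenile-low transcripts: all 32 rising ones, 394 of 615 steady, 28 of 313 intermediate and 18 of 2530 co-varying ones. That all 32 passed was nearly fixed by their choice, as far below day 0 in juveniles and above it at day 7. The steady and co-varying parts were split by their spread between trunk libraries, which also sets how easily this test calls them. Their counts therefore do not compare their levels at day 7. GDAG01017044.1 stood at 18.9 ± 1.82 CPM at day 7 and 3.01 ± 0.229 CPM in juveniles, 6.28-fold apart (edgeR adjusted p = 7.3e-09). GDAG01071011.1 was 2.62-fold and GDAG01033469.1 3.01-fold higher at day 7 than in juveniles (edgeR adjusted p = 2.3e-07 and 2.3e-05). The count of 3933 was 2464 without juvenile replicate 2, and 5986 without the 3 libraries left out together.

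Fold changes of the regenerating fragments were set beside those of juveniles, both against day 0, to ask whether the fragments moved along the difference between trunk and juvenile. Across the 46736 transcripts, which are not independent replicates, the correlation was 0.752 for day 3, 0.733 for day 5 and 0.912 for day 7. Libraries with their group means removed and then regrouped, which share the day 0 libraries but hold no group difference, gave correlations of up to 0.845, 1 and 0.908 in 100 regroupings. No correlation can pass the maximum of 1 for day 5, so that maximum does not test the value of 0.733. The mean of the regroupings for day 5 was 0.526. The value for day 7 passed its maximum of 0.908 by little. It fell below 0.908 with any 1 day 7 or juvenile library left out (0.882 to 0.907). Without day 0 replicate 3 it was 0.893, and above a mean log2 CPM of 2 it was 0.878. The covariance, which shared libraries raise by the same amount with or without an effect, was 0.581, 0.507 and 1.16, against means of 0.0507, 0.0592 and 0.0476 and maxima of 0.224, 0.2 and 0.176 in the regroupings. At day 7, 2253 of the transcripts higher and 6485 of those lower than at day 0 were called in the same direction in juveniles, against 445.3 and 1421 for independent lists. Simulations of unchanged groups sharing the day 0 libraries gave an edgeR overlap of 0, but such groups give few calls at all, so this is no measure of what the shared libraries add to lists with real changes. Part of the excess may come from those libraries, which could not be divided. The change from day 3 to day 7, which shares no library with the juvenile comparison, correlated with it at 0.807 (Spearman's rho 0.396), with a maximum of 0.734 in the regroupings, and the change from day 5 to day 7 at 0.821 (rho 0.417), with a maximum of 0.633. Between days 3 and 5 the correlation was -0.181 (rho -0.133), and it was 0.009 without day 3 replicate 1 and 0.028 above a mean log2 CPM of 2. The regroupings for that step had a mean of 0.0785 and a maximum of 0.851. Their minimum was not kept, so the negative value cannot be placed among them. The correlation for day 3 to day 7 fell below 0.734, the maximum in all-library regroupings, when 1 of 2 libraries was left out. It was 0.673 without day 7 replicate 2 and 0.687 without day 3 replicate 3. It was also below that maximum without the low-count filter (0.639) and without the 3 libraries left out together (0.477). With any other single library left out it was 0.766 or more, and above a mean log2 CPM of 2 it was 0.877. Its excess over the regroupings thus depended on 2 libraries and on the filter, and the regroupings were not repeated for these settings. That for day 5 to day 7 was lowest without the filter (0.674) and, with 1 library left out, without day 7 replicate 2 (0.734), both above its maximum of 0.633.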

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

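The tests of sequencing depth, of 1 common source, of a batch, of a relative rise and of the spread between libraries, and the comparison of day 7 with day 3, were chosen after the results had been seen; the regroupings of libraries were chosen before. The grouping of the rising records was chosen before its own outcome was seen, but on a set found in these data. The change from day 0 differed between times in 566 transcripts for day 7 against day 3, in 374 for day 7 against day 5, and in 9 for day 5 against day 3, each by the edgeR test of the difference itself. Without day 3 replicate 1 the first count was 347, and without day 7 replicate 2 it was 332; DESeq2 called 1330 and a fit of these 2 groups alone 311. The 374 became 613 without day 0 replicate 3, 199, 174 and 197 without day 5 replicate 1, 2 or 3, and 232, 196 and 239 without day 7 replicate 1, 2 or 3. The 9 became 22 without day 0 replicate 3, and 3 without day 3 replicate 3 or without day 5 replicate 1.

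The small number of changes from day 3 to day 5 was weighed against the spread between libraries of 1 group. Without day 0 replicate 3, day 3 replicate 3 and day 7 replicate 2, 539 transcripts were called in place of 9, 428 of them higher at day 5 and 256 of them co-varying. This does not isolate the spread, since leaving out day 3 replicate 3 also lowers the day 3 level of the co-varying transcripts. They took 2.87% of the counts in that library and 0.718% and 0.848% in the remaining day 3 libraries. At day 5 they took 1.07%, 1.69% and 2.05%. Leaving out day 3 replicate 3 alone gave 3 calls. Of the 10 splits of the 6 libraries, 2 called at least as many transcripts as the real one, which called 4; the highest other called 641. That split set day 5 replicate 1 with day 3 replicates 1 and 2 against the other 3 libraries, so it follows a structure of the samples other than time. It joins the libraries with the 3 lowest shares of co-varying transcripts among the 6. Whether the spread or a small true difference between days 3 and 5 keeps the count low cannot be told apart with these libraries, and 3 libraries against 3 are too few for a share of splits under 0.05.

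Libraries of 1 trunk group differed along a single axis in the juvenile-low transcripts, which carried 85.8% of the variance within groups; 2530 transcripts followed it. Depth is argued against: the 3 day 7 libraries, whose totals differed by 1.11-fold, differed by 8.08-fold in the median CPM of these transcripts. A single source that carries all juvenile-low transcripts, such as 1 tissue present in differing amounts, is argued against as well, because 55.3% of the 179 juvenile-low transcripts above a log2 CPM of 6 at day 0 (99 of them) correlated with the axis below 0.5. A batch that follows the replicate number cannot be told apart from a difference between the animals: replicate 3 had the highest score in 4 of 4 trunk groups (53.6, 60.9, 15.8 and 65.1 at days 0, 3, 5 and 7), but the labels do not tie the number to a batch. No other biological explanation was tested, since the labels give no stage or size for single libraries.

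The 32 juvenile-low transcripts that rose during regeneration were weighed against 2 explanations. A relative rise left by the fall of the other juvenile-low transcripts is argued against by size. Juvenile-low transcripts together held 12.1% of the counts at day 0, too little for their loss to raise the others by as much as 1.5-fold. The median fold of the 32 from day 0 to day 7 was 3.82 (quartiles 3.01 and 4.14). They were chosen as higher at day 7, so a median above 1.5 was largely set by the choice. Outside the juvenile-low and juvenile-high sets 4172 transcripts also fell. Their share was not computed. A relative rise left by any transcripts that fell would lift all others by the same factor. Over all 46736 transcripts the median log2 fold change from day 0 to day 7 was 0.041 after scaling. The scaling factors were 0.893 to 0.933 at day 0 and 0.984 to 1.02 at day 7. These values leave no room for a common rise near 3-fold, which argues against such a rise for the 32 as a set. The other explanation, a few transcripts listed as many records, was tested only for copies that keep a constant ratio between libraries. The records fell into 24 such groups, the largest with 4 records. Records were joined where the SD of their log2 ratio over all 15 libraries was at most 0.2. Those libraries include juveniles, where the set is scarce and counting noise larger. Records of 1 gene that differ by more would stay apart, so the number of genes cannot be told from the 24. A hypothesis in which these transcripts mark a part of regeneration that intact juveniles lack was not tested and cannot be pursued without gene names. By the choice of the set they were already above juveniles at day 0, with 1.02% ± 0.0654 against 0.11% ± 0.0361 of the counts. Body part and stage differ together in the comparison with juveniles.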

How the results depend on the processing

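Leaving out 3 libraries together and the other folds for the juvenile-low set were chosen after the data had been seen; day 7 against day 3, the sets, the counts outside the range of day 0 and juveniles and the correlations of later steps with juveniles were added then too, and run under the alternatives fixed before. Over all results 1013 alternatives were run. Of these 901 stayed within 1.5 times the count or within the spread, or kept the sign and call of a named transcript. A further 110 moved more, 0 lost the call of a named transcript, and 2 turned the sign of a correlation. That of day 5 against day 3 with juveniles, -0.181, was 0.009 without day 3 replicate 1 and 0.028 above a mean log2 CPM of 2. Many of the 901 could hardly move. A group's share of counts changes little when a library of another group is left out, and a 2-fold threshold cannot change sets defined at 4-fold. The 901 is therefore no measure of how stable the results are. The majority direction of a count of calls turned in 1 case, day 5 against day 3 without day 3 replicate 2 (3 higher and 5 lower). Where no cause is given it was not tested. Gene list tests were not run, since identifiers could not be matched to names. Depth and spread limit small changes: the simulated test of day 3 against day 0 recovered 6% of 1.5-fold changes. RLE scaling moved no result beyond these bounds.

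With each fit holding only the groups compared, and so fewer residual degrees of freedom, calls fell to 664, 2103 and 5162 for days 3, 5 and 7 against day 0, 4 for day 5 against day 3 and 311 for day 7 against day 3, and rose to 914 for day 7 against day 5. Transcripts called alike at all 3 days were 500, those above and below both day 0 and juveniles at day 3 were 119 and 103, and juvenile-high 61. Lower at day 7 than at day 0 were 804 juvenile-low and 290 co-varying transcripts, 126 steady ones were lower at day 3 and 155 lower at day 7 than at day 3, and 29 juvenile-high ones were higher at day 7.

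The 2-fold threshold, a subset by construction, left 886, 910 and 4879 calls for days 3, 5 and 7 against day 0, 179 for day 7 against day 5, 324 for day 7 against day 3, 5983 for juveniles against day 0, 1050 for day 7 against juveniles and 402 called alike at all 3 days; above and below both day 0 and juveniles it left 117 and 68 at day 3 and 130 and 36 at day 7. DESeq2 called 71 for day 5 against day 3, 1235 for day 7 against day 5 and 1330 for day 7 against day 3.

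Without the low-count filter, 21 were called for day 5 against day 3, 212 and 139 lay below both day 0 and juveniles at days 3 and 7, juvenile-high were 316, of which 99 were higher at day 7 than at day 0, steady were 1149, and fold changes of juveniles correlated with those of day 7 at 0.872, of day 7 against day 3 at 0.639 and of day 7 against day 5 at 0.674. Above a mean log2 CPM of 2 the correlation for day 7 was 0.878. Without the 3 libraries left out together, calls were 539 for day 5 against day 3 and 1578 for day 7 against day 5. Day 7 against juveniles then had 5986 calls. Juvenile-high were 243, and steady transcripts lower at day 7 than at day 3 were 109. These correlations with day 7, day 7 against day 3 and day 7 against day 5 were 0.859, 0.477 and 0.704.

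With the replicate block, calls were 7238 for day 3 against day 0, 2628 for day 7 against day 5 and 1592 for day 7 against day 3. Called alike at all 3 days were 3719. The block changed no other call by more than 1.5 times. For day 3 and day 0 each number correlated best with its own, which does not establish a pairing. In the comparisons other than day 3 with day 0, own numbers correlated best for 1 or 2 of 3 libraries, a hint from the data only. A 2-fold bound of the juvenile-low set gave shares of 15.3%, 10.2%, 9.63%, 8.04% and 1.89% at days 0, 3, 5 and 7 and in juveniles, 54 rising transcripts with 1.13% at day 0 and 0.166% in juveniles, and 1132 steady ones, 370 of them lower at day 3; an 8-fold bound gave 6.74% at day 5 and 0.226% in juveniles, and 19 rising transcripts with 0.94% at day 0.

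With 1 library left out, calls ranged from 1795 to 5332 for day 3, 2331 to 4492 for day 5 and 6510 to 11585 for day 7 against day 0, 3 to 22 for day 5 against day 3, 174 to 613 for day 7 against day 5, 332 to 660 for day 7 against day 3, 2464 to 4326 for day 7 against juveniles, 4426 to 9302 for the F test and 1281 to 2492 called alike at all 3 days. Above and below both day 0 and juveniles were 224 to 473 and 195 to 394 at day 3, and 343 to 585 and 115 to 269 at day 7. Juvenile-high were 132 to 278, of which 45 to 119 were higher at day 7; lower at day 7 than at day 0 were 1504 to 3539 juvenile-low and 766 to 2601 co-varying, and 123 to 273 steady ones were lower at day 3. The correlation with juveniles was 0.734 to 0.813 for day 7 against day 5 and -0.406 to 0.009 for day 5 against day 3. With groups of 2 the filter keeps more scarce records.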

Other observations

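The counts of transcripts above or below both day 0 and juveniles were chosen after the data had been seen, and so was the comparison of day 7 with day 3; the regroupings were chosen before. Some transcripts in regenerating fragments lay outside the range between trunk and juvenile. At day 3, 377 transcripts were higher than both day 0 and juveniles and 416 lower than both, against 156.2 and 195.3 for independent lists. Simulations of unchanged groups gave at most 1, but such groups give few calls at all, so what the shared day 3 libraries add to these counts was not measured. The median of the 377 was 14.5 ± 0.906 CPM at day 3, against 8.55 ± 0.473 at day 0 and 7.13 ± 0.178 in juveniles (SD, n = 3), and 14.3 ± 0.415 at day 7. Of the 377, 240 were called higher than at day 0 at day 5 and 271 at day 7, and 12 were lower at day 7 than at day 3. The 416 had a median of 14.1 ± 0.549 CPM at day 3, against 20.6 ± 0.6 at day 0, 20.2 ± 0.568 in juveniles and 16.2 ± 0.79 at day 7, where 49 were called higher than at day 3. Both sets were chosen on day 3, so their levels there are raised or lowered by the choice. Without day 3 replicate 1 the counts were 224 and 195, without day 3 replicate 2 the lower count was 260, and in fits of the compared groups alone they were 119 and 103.

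At day 7, 524 transcripts were higher than both day 0 and juveniles and 259 lower than both, of which 223 and 143 were already so at day 3. The 524 took 3.88% ± 0.177 of the counts at day 0, 6.47% ± 0.452 at day 3, 7.02% ± 0.331 at day 5, 8.49% ± 0.656 at day 7 and 3.22% ± 0.153 in juveniles. For the 259, independent lists would share 240.3. The 524 became 343 without day 7 replicate 1, and the 259 became 115, 155 and 165 without day 7 replicate 1, 2 or 3 and 154 without juvenile replicate 2. The juvenile-low and juvenile-high transcripts apart, 3589 of the 43146 other tested transcripts were higher and 4172 lower at day 7 than at day 0.

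For the F test over the 4 trunk groups, the 12 trunk libraries were regrouped at random. In a fit of these groups alone the real grouping called 4924 transcripts, and the highest of the other groupings called 3. Of 40 groupings 1, the real one, called as many, which argues against chance but with 40 groupings does not exclude it. Such regrouping treats the libraries as exchangeable, which the labels do not establish. For the pairwise comparisons, each fitted alone, the 10 splits of 6 libraries are too few for a share under 0.05. The real split called 664 transcripts for day 3, 2103 for day 5 and 5162 for day 7 against day 0, 11290 for juveniles against day 0, 4658 for day 7 against juveniles and 311 for day 7 against day 3, and the highest other split called 0 in each of these. For day 7 against day 5 the real split called 914 and the highest other 1. In these 7 comparisons 1 split, the real one, called as many transcripts, and 2 did for day 5 against day 3.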
